A study of Mus musculus with 4 samples.

How the data were processed

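Primary pancreatic acinar cells from C57BL/6J mice, kept with 25 ng/ml epidermal growth factor, received an adenovirus encoding either estrogen-related receptor γ (ERRγ, gene Esrrg) or green fluorescent protein (GFP). The multiplicity of infection was 100 and cells were collected after 36 h, per the labels' protocols. Libraries were made from 500 ng total RNA with a Lexogen QuantSeq kit, which primes on the poly(A) tail and reads transcript ends. The labels give 2 libraries for each virus, numbered 1 and 2.

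The deposited files hold 1 table of whole-number read counts per gene symbol for each of the 4 libraries, with no normalization. Bowtie2, edgeR and the mouse build mm10 are named in the submitters' processing notes, without versions. The read counter, the gene annotation, the use of strand, the treatment of reads that match several places and any filter are not given in the sources used here. Each table has 23282 rows and 23238 distinct symbols, because 35 symbols stand on 79 rows; these rows were kept apart. Counts totalled 10480878 and 10645277 in the ERRγ libraries 1 and 2, and 10105604 and 11012351 in the GFP libraries 1 and 2. A floor of 3 counts in a library corresponds to between 0.268 and 0.307 CPM (counts scaled to a common library total). Transcript-end reads were amplified by PCR and no molecular identifiers are mentioned, so intervals and floors cover counting error only.

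How the authors counted the deposited reads could shift single genes in several ways. Reads in overlapping genes may be given to both or to either: 49 pairs of neighbouring rows with a mean of at least 50 counts carry counts that differ by no more than 5%, such as Wdr89 and Rplp2-ps1. Of the 82 genes named by the rule below, 13 overlap another coding gene (Esrra, Ccl2, Timp2, Ndufb2, Atp5a1, Acadvl, Mrpl14, Mrpl13, Manf, Ppp1r15a, Shmt2, Prdx5 and Ckmt1). Near-identical families such as the amylases, trypsinogens, Prl3d prolactins and Klra receptors can share reads, and their single values are uncertain. The length of a transcript has little bearing on a count when each transcript is read once near its end.

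Genes were tested in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with the group given and a minimum count of 10, which left 13070 of the 17888 rows that had a count. Library sizes were scaled by TMM, with factors of 1.071 and 0.952 for ERRγ libraries 1 and 2 and 0.968 and 1.013 for GFP libraries 1 and 2. A model with the group alone was fitted to all 4 libraries, with 2 residual degrees of freedom, by glmQLFit and tested by glmQLFTest with a fitted prior count of 0.125. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and all tests were two-sided. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM are on TMM library sizes. Where a group had no count in either library, the fold is a lower bound against 3 counts in each library of that group; with a total of 1 to 3 counts in that group, the ratio is given with an exact 95% counting interval.

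The 32 gene lists, the tests and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1), which asks whether a list's genes differ more than the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists tested. None of the 13 listed mitochondrially encoded genes had a row under its symbol, so that list was not tested. The respiratory chain lists therefore cover nuclear genes only. Camera with a correlation estimated for each list, and fry, which asks whether a list's genes move on balance in either direction, were run beside it. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

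The named genes followed a rule fixed before the data were examined. Esrrg, Esrra and Esrrb were named whatever they showed, and so were Ptf1a, Bhlha15, Cpa1, Krt19, Sox9, Ppargc1a, Atp5b and Idh3a. The 8 largest rises and the 8 largest falls were named among genes past the threshold with non-overlapping groups, a mean of at least 10 CPM and a symbol that is not a predicted gene. For each list past the threshold the 3 members with the smallest p were named, and 1 for each other list with a member past it. Members named only to spell out a count of 5 or fewer, and genes marked so in the text, were chosen after their values were seen; a single-gene result in 1 such count is not reported here. Positions come from GENCODE M21 on GRCm38, the assembly behind mm10, matched by symbol; 82 of the 82 named genes and 12966 of the 13070 tested rows had a match.

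The test was tried on simulated counts with the real genes' means and library sizes, in 10 draws of 13070 genes with 200 changed. The changed genes had a mean of at least 5 CPM and rose and fell in equal number, and all genes varied independently. The shares recovered therefore do not cover genes of lower level. With the spread of the fitted trend, 13.2% of genes changed 1.5-fold, 63.2% changed 2-fold, 95.8% changed 3-fold and 98.2% changed 4-fold were recovered, and 3.2% of calls were false. With a separate spread for each gene, the shares were 9.2%, 57.0%, 89.0% and 97.4%, and 11.5% of calls were false, above the nominal level. Changes of 1.5-fold are therefore mostly missed with 2 libraries a group, and the share of false calls can exceed the threshold.

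Alternatives were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, removal of genes above 1% of counts, a replicate block, removal of each library in turn, an adjusted p threshold of 0.1, and a log2 fold change of at least 1. Removal of Rn45s (pre-ribosomal RNA) and summing of rows with a shared symbol were added after seeing the data.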

Results

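Transcript levels were measured by transcript-end sequencing in primary mouse pancreatic acinar cells, the cells of the exocrine pancreas that make and secrete digestive enzymes. The cells carried an adenovirus, a vector that delivers a gene into dividing and resting cells alike. It encoded either ERRγ, an orphan nuclear receptor that binds DNA at estrogen-related receptor elements and is known for its role in oxidative metabolism of heart and other high-energy tissues, or GFP as the control. There were 2 libraries in each group, with 10.48 and 10.65 M counts for ERRγ libraries 1 and 2 and 10.11 and 11.01 M counts for GFP libraries 1 and 2. The pre-ribosomal RNA Rn45s took 9.48%, 11.1%, 14.4% and 10.4% of these counts in the same order (exact 95% intervals, 9.462 to 9.498, 11.098 to 11.136, 14.367 to 14.41 and 10.391 to 10.427). The labels do not say that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Both pairs differed by far more than counting error (chi-square over its degrees of freedom, 24.2 for ERRγ and 15.2 for GFP). Values are mean ± SD with n = 2 unless stated.

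The design has a single comparison, which asks how the transcriptome of cells labelled as acinar changes when ERRγ is overexpressed. The libraries held few transcripts of acinar identity: digestive enzyme genes took at most 0.0178% of counts, against 1.97% to 2.50% for Clu, which encodes the chaperone clusterin and is induced in injured epithelia. The values are therefore those of these cultures, not of acinar cells that keep their enzyme expression. Esrrg, the gene that the virus carried (chromosome 1, 187608791 to 188214885, plus strand, GRCm38), rose from 9.20 ± 0.569 CPM with GFP to 707 ± 816 CPM with ERRγ (log2 fold change 6.26, SE 1.00, adjusted p = 0.0109). Its counts were 1453 and 12994 in ERRγ libraries 1 and 2 and 86 and 107 in the GFP libraries, so that library 2 held 9.9 times the CPM of library 1. Against the GFP mean, Esrrg was 14.1 times as high in ERRγ library 1 and 140 times as high in library 2. A transcript-end read counts a transgene at Esrrg only if the construct keeps sequence that maps there, so these values need not measure the whole of the introduced transcript. Of the related receptors, Esrra (chromosome 19, 6910977 to 6921813, minus strand) stood at 126 ± 9.83 CPM with ERRγ and 128 ± 12.0 CPM with GFP (log2 fold change −0.03, SE 0.14, adjusted p = 0.939; −0.12 to 0.072 when a library was left out). Esrrb (chromosome 12, 86361117 to 86521628, plus strand) had 16 and 34 counts with ERRγ and none with GFP, at least 8.31-fold higher (adjusted p = 0.0255). The coactivator gene Ppargc1a, with 3 and 5 counts against 5 and 9, was too low to test. In the list of ERR receptors and coactivators, Esrrg and Esrrb were the 2 of 9 tested members that rose, also when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.107). It passed without ERRγ library 1 or ERRγ library 2, when the spread comes from the GFP pair alone. The list holds Esrrg, the gene that the virus carried, so its upward lean is in part built in. Its mean log2 fold change was 1.61 and its median 0.35, and a pass says nothing about the members other than Esrrg and Esrrb. The call for Esrrg ended without GFP library 1 (log2 fold change 6.19, adjusted p = 0.168) or GFP library 2 (6.32, adjusted p = 0.127), and that for Esrrb likewise (adjusted p = 0.193 and 0.159), since the spread then comes from the ERRγ pair alone. With limma-voom the call for Esrrg ended too (log2 fold change 5.46, adjusted p = 0.0623). Without ERRγ library 2 the log2 fold change of Esrrg was 3.81, and without ERRγ library 1 it was 7.12.

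Across the transcriptome more genes rose than fell with ERRγ. The genes that follow were taken by size among those with a mean of at least 10 CPM, and genes of lower level with folds as large are not listed here. Pgm5, a phosphoglucomutase relative found at cell adhesions, went from no count in either GFP library to 433 and 335 counts, at least 124-fold. Nr0b2, which encodes the corepressor SHP, went from none to 263 and 213 counts, at least 77.2-fold. Prl3d1 and Prl3d2, near-identical placental lactogen genes of chromosome 13, had 405 and 186, and 290 and 158 counts, against 3 and 2 counts in the GFP libraries together (ratios 193, 65.8 to 939, and 220, 60.4 to 1820). Ppp2r2c, a regulatory subunit of protein phosphatase 2A, rose 122-fold to 196 ± 19.3 CPM. AI593442 rose 42.7-fold and the diacylglycerol kinase gene Dgkk 32.6-fold. Single GFP libraries moved some of these folds: without GFP library 1 and without GFP library 2 the log2 fold change went from 6.93 to 7.90 and 6.31 for Ppp2r2c and from 5.42 to 6.345 and 4.804 for AI593442. Among the falls, Akr1c18, which encodes a progesterone-metabolising reductase, dropped 15.3-fold, from 28.7 ± 14.6 to 1.84 ± 1.06 CPM. The tight-junction gene Cldn1 fell 5.25-fold, from 84.8 ± 5.07 to 16.2 ± 2.42 CPM, and Xirp2, an actin-binding protein gene, fell 5.19-fold, from 443 ± 133 to 85.3 ± 0.237 CPM. Timp2, an inhibitor of matrix metalloproteinases, fell 3.08-fold, from 738 ± 7.93 to 239 ± 28.6 CPM. The chloride transporter gene Clcn5 (from 24.7 ± 7.83 to 6.16 ± 0.75 CPM), the monocyte chemokine gene Ccl2 (3.93-fold), the protease inhibitor gene Serpinb2 (3.78-fold) and Plekhs1 (3.18-fold) fell as well. The calls for Akr1c18 (adjusted p = 0.0659), Clcn5 (0.117), Ccl2 (0.0559) and Serpinb2 (0.357) ended without GFP library 1, and that for Serpinb2 also with limma-voom (0.119). The log2 fold change of Serpinb2 went from −1.92 to −1.05 without GFP library 1, and that of Akr1c18 from −3.94 to −3.31 without GFP library 1 and −4.71 without ERRγ library 1.

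In all, 661 genes rose and 233 fell among the 13070 tested with edgeR's quasi-likelihood test, which is 6.84% of them, and 73.9% of the calls were rises. Rises of at least 2-fold numbered 404 and falls of that size 71, and 27 genes that rose had no count in either GFP library. The median log2 fold change of all genes tested was −0.01. The groups did not overlap in 54.0% of genes tested, where chance gives 33.3%. The first principal component held 63.9% of the variance and parted the groups; the second held 20.9% and lay mainly between the ERRγ libraries. Without GFP library 1, 92 genes rose and 7 fell, and without GFP library 2, 119 rose and 20 fell; without ERRγ library 1, 1597 rose and 1098 fell, and without ERRγ library 2, 974 rose and 640 fell. Of the 66 named genes past the threshold, most lost it without GFP library 1 and most without GFP library 2. In the fits of all 4 libraries, 60 kept it wherever they were tested. Esrrb, counted among these 60, was too low for the 5 CPM filter. Pgm5, Nr0b2, Prl3d1, Prl3d2, Ppp2r2c, AI593442, Dgkk, Cldn1, Xirp2, Plekhs1, Timp2, Idh3a, Mpc1, Timm8a1, Car2, Ckb and Got1 kept their calls in every fit listed in the closing section.

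**Figure D1:**
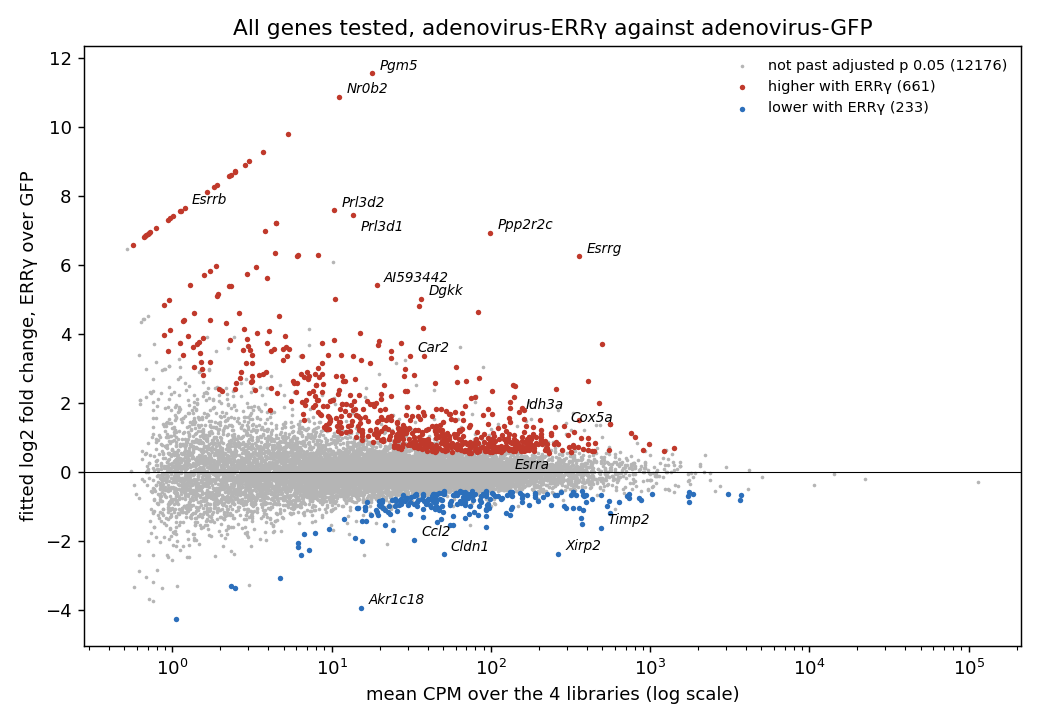
Fitted log2 fold change (ERRγ over GFP) against the mean CPM of the 4 libraries on a log axis, 1 point per gene tested; red points are the 661 genes that rose and blue points the 233 that fell. Points on the rising edge at the upper left are genes with no count in either GFP library, whose fitted fold depends on the prior count.

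**Figure D2:**
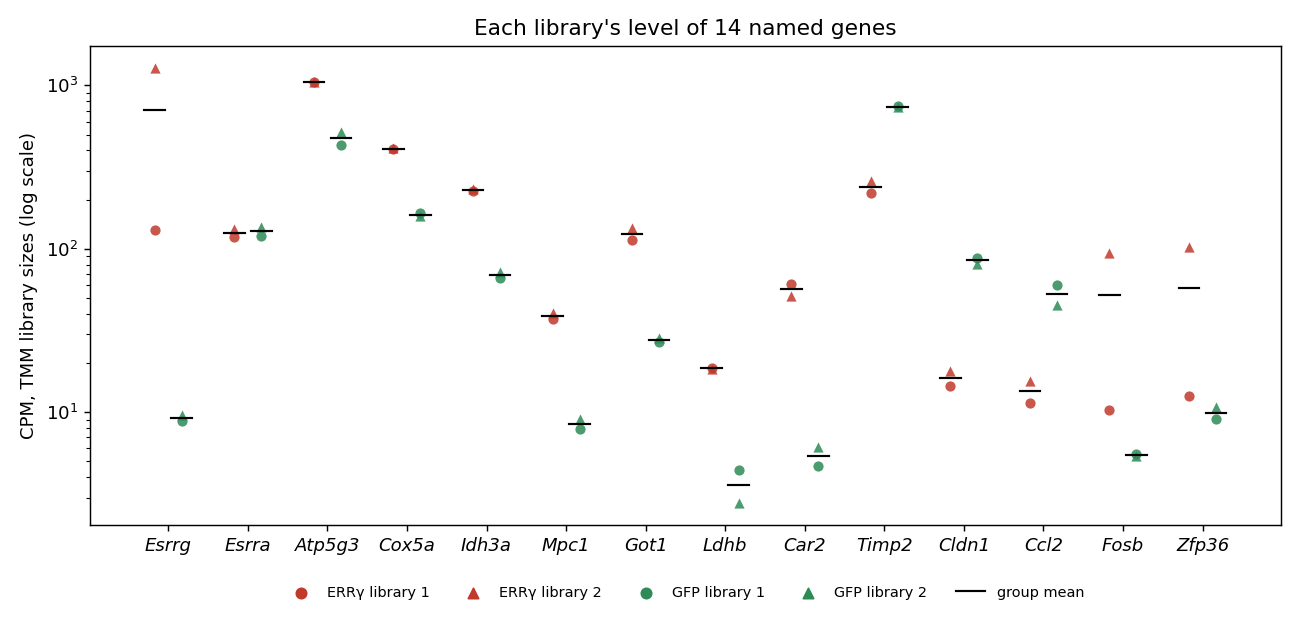
CPM on a log axis of selected named genes in each library; circles are libraries 1, triangles libraries 2, red ERRγ, green GFP, and bars the mean of 2 libraries. The metabolic genes from Atp5g3 to Got1 lie close together within each group, whereas Esrrg, Fosb and Zfp36 are far apart between the ERRγ libraries.

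In the 4 respiratory chain lists, 5 to 13 genes each rose with ERRγ, and none of the tested members fell. Cox5a, a subunit of cytochrome c oxidase, rose 2.53-fold, from 162 ± 5.92 to 410 ± 4.79 CPM (log2 fold change 1.34, SE 0.13, adjusted p = 0.00168). Atp5g3, which encodes the rotor subunit of ATP synthase, rose 2.19-fold, from 477 ± 60.6 to 1045 ± 1.66 CPM. Ndufb2 of complex I rose 2.06-fold and cytochrome c itself, Cycs, 1.87-fold. The plot of list members shows the medians of these lists to the right of zero. Of 37 genes in the complex I list, 13 rose, Ndufa5 (1.87-fold) and Ndufa6 (1.81-fold) among them, and 22 when adjusted over the list alone. One of the 13 was Ndufa4, also named Coxfa4, which is a subunit of cytochrome c oxidase. The list's median log2 fold change was 0.45 (camera adjusted p = 1.81e-09, and 0.418 with an estimated correlation). Complexes II and III had 5 of 14 genes up, namely Cycs, Uqcrfs1 (1.85-fold), Uqcr10 (1.70-fold), Uqcrc2 and Cyc1, and 10 when adjusted over the list alone (median 0.53, camera adjusted p = 5.8e-06; adjusted p = 0.514 with an estimated correlation). The complex IV list also holds assembly genes such as Cox10 and Surf1. In it 9 of 18 genes rose, with Cox7b at 1.96-fold and Cox6a1 at 1.79-fold, and 13 when adjusted over the list alone (median 0.63, camera adjusted p = 6.77e-09, and 0.411 with an estimated correlation). ATP synthase had 10 of 17 genes up, with Atp5a1 at 1.96-fold, Atp5g1 at 1.93-fold and Atp5b at 1.75-fold, and 14 when adjusted over the list alone (median 0.65, camera adjusted p = 3.5e-09; adjusted p = 0.411 with an estimated correlation). These 4 camera calls held without any single library, but the named genes' own calls ended without GFP library 1 (adjusted p of 0.056 for Cox5a to 0.265 for Atp5b) and without GFP library 2 (0.0507 for Cox5a to 0.157 for Uqcr10), as did those for Uqcrc2 (0.313 and 0.239) and Cyc1 (0.266 and 0.18). Ndufb2 overlaps Gm42420 on the same strand and Braf on the opposite strand, and Atp5a1 overlaps Haus1 on the opposite strand. The counts of Ndufb2 and Atp5a1 could therefore include reads of these neighbours.

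Of 21 genes of pyruvate entry and the tricarboxylic acid (TCA) cycle, 9 rose with ERRγ, 18 when adjusted over the list alone, and none fell (median 0.60, camera adjusted p = 1.17e-12; adjusted p = 0.411 with an estimated correlation). Mpc1 and Mpc2, which form the mitochondrial pyruvate carrier, rose 4.58-fold, from 8.47 ± 0.839 to 38.9 ± 2.27 CPM, and 2.17-fold, from 33.6 ± 2.37 to 72.8 ± 1.13 CPM. Idh3a, the catalytic subunit of NAD-dependent isocitrate dehydrogenase, rose 3.32-fold, from 69.3 ± 3.87 to 230.2 ± 4.76 CPM (log2 fold change 1.73, SE 0.13, adjusted p = 0.000526). Mitochondrial import and dynamics had 11 of 32 genes up, 20 when adjusted over the list alone (median 0.42, camera adjusted p = 3.56e-09; adjusted p = 0.411 with an estimated correlation). These included the import chaperone gene Timm8a1 (3.10-fold), the outer-membrane channel gene Vdac1 (2.15-fold) and the inner-membrane translocase gene Timm22 (2.02-fold). In the mitochondrial ribosome list, Mrpl14 (1.75-fold), Mrpl13 (1.67-fold) and Mrpl12 (1.49-fold) were the 3 of 48 genes that rose, 4 when adjusted over the list alone (median 0.18, camera adjusted p = 0.0149; adjusted p = 0.411 with an estimated correlation). Fatty acid oxidation did not pass as a list (camera adjusted p = 0.444). There Acadvl, the very-long-chain acyl-CoA dehydrogenase gene, rose 2.03-fold and Pdk4, an inhibitor of pyruvate dehydrogenase, fell (log2 fold change −0.99, adjusted p = 0.0238), out of 23 genes with a median of 0.10; 4 rose and 2 fell when adjusted over the list alone. The calls for Idh3a, Mpc1 and Timm8a1 held without any single library, whereas without GFP library 1 and without GFP library 2 those for Mpc2 (adjusted p = 0.0711 and 0.0806), Vdac1 (0.11 and 0.0673), Timm22 (0.107 and 0.0833), Acadvl (0.111 and 0.0833), Pdk4 (0.215 and 0.148) and the Mrpl genes (0.133 to 0.256 and 0.162 to 0.306) ended. Acadvl, Mrpl14 and Mrpl13 overlap the genes Dvl2, Tmem63b and Mtbp.

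**Figure D3:**
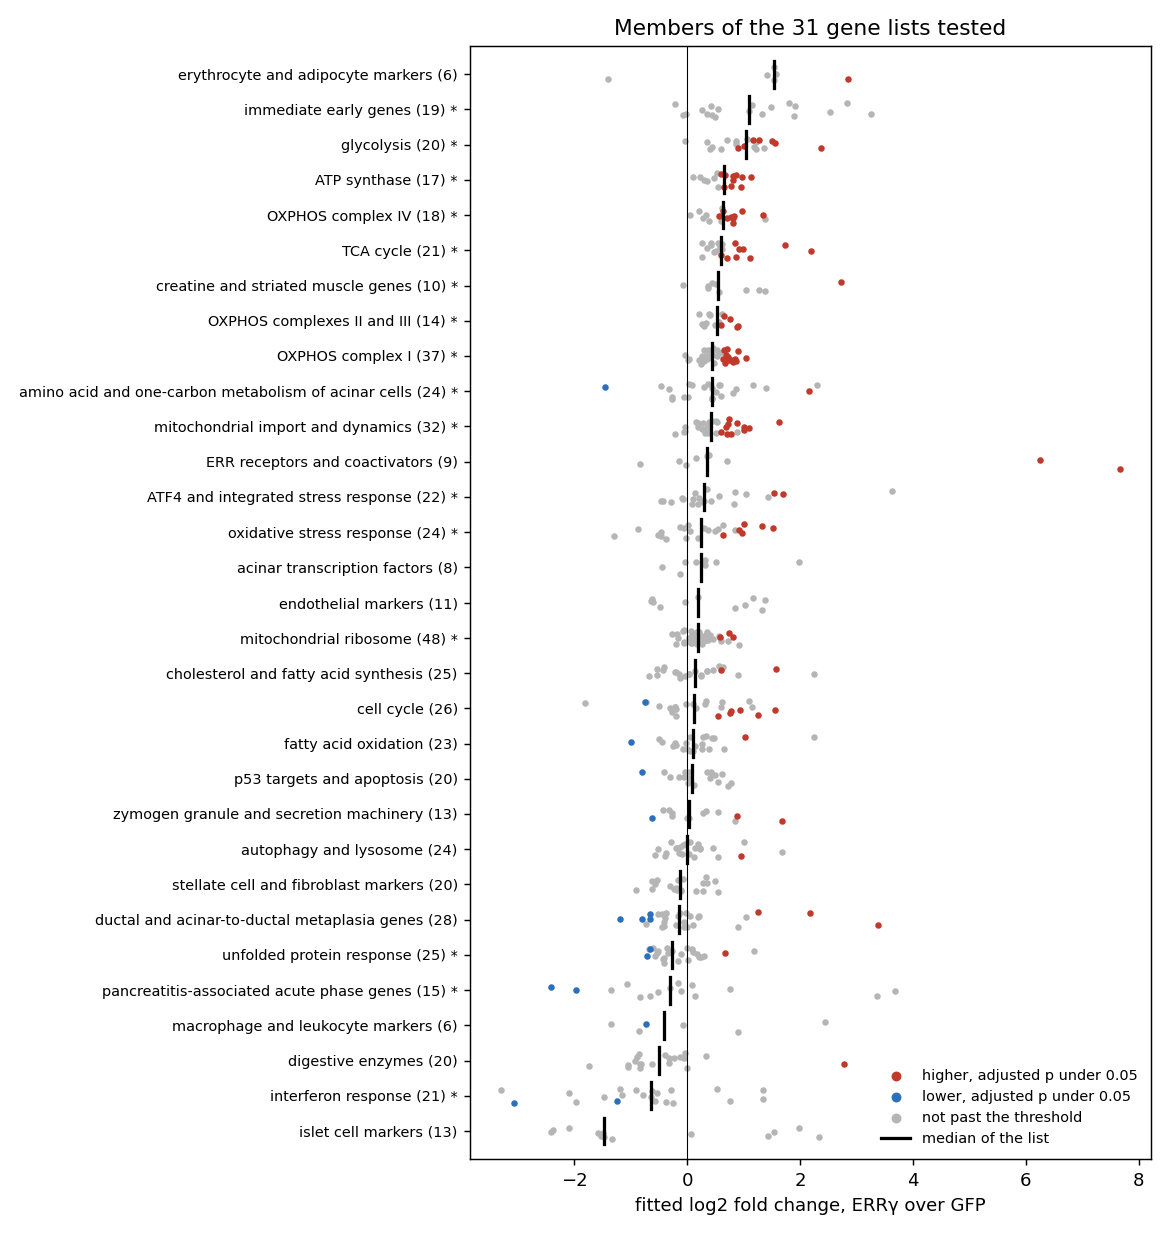
Fitted log2 fold change (ERRγ over GFP) of each tested member of the 31 gene lists, with the number tested in brackets and a star where camera passed at an adjusted p of 0.05; black bars are list medians, red and blue points members that rose or fell over all genes tested. The respiratory chain and TCA lists have medians from 0.45 to 0.65 and no member that fell.

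Of 20 glycolysis genes 7 rose, and the lists of amino acid and of creatine metabolism had 1 gene up each. Hk1, the first enzyme of glycolysis, rose 2.93-fold, from 66.3 ± 1.13 to 194 ± 39.1 CPM, Ldhb, which encodes the lactate dehydrogenase subunit of oxidative tissues, rose 5.17-fold, and the lactate transporter gene Slc16a1 rose 2.83-fold. Got1, a cytosolic aminotransferase of the malate-aspartate shuttle, rose 4.46-fold, from 27.6 ± 1.30 to 123 ± 14.1 CPM. The creatine kinase gene Ckb rose 6.64-fold, from 22.2 ± 12.3 to 147 ± 2.61 CPM (log2 fold change 2.73, and 3.43 without GFP library 1). Glycolysis had 7 of 20 genes up, 13 when adjusted over the list alone, and none down (median 1.04, camera adjusted p = 1.46e-09; adjusted p = 0.514 with an estimated correlation). Its median member was 0.74 (log2) higher in ERRγ library 2 than in ERRγ library 1, against 0.08 between the GFP libraries. Without ERRγ library 2 the glycolysis list still pointed upward. There the log2 fold changes of the members named above were 1.33 for Hk1, 2.38 for Ldhb and 1.185 for Slc16a1. In the creatine and striated muscle list Ckb was the 1 of 10 genes that rose, 2 when adjusted over the list alone (median 0.54, camera adjusted p = 0.00148; adjusted p = 0.411 with an estimated correlation). Ckmt1 (log2 fold change 1.05, adjusted p = 0.0647) and Cox7a1 (1.38, adjusted p = 0.124), which is also in the complex IV list, did not pass. Without ERRγ library 1 the log2 fold change of Ckmt1 was 1.23. Amino acid and one-carbon metabolism had Got1 up and Cbs, the cystathionine β-synthase gene, down 2.75-fold, out of 24 genes, and 6 up and 1 down when adjusted over the list alone (median 0.43, camera adjusted p = 0.0456; adjusted p = 0.66 with an estimated correlation). Slc7a8 in that list did not pass (1.39, adjusted p = 0.0645), and its log2 fold change was 1.425 without ERRγ library 1. In cholesterol and fatty acid synthesis 2 of 25 genes rose, Idi1 (2.98-fold) among them, 6 up and 1 down when adjusted over the list alone, and the list did not pass (median 0.14, camera adjusted p = 0.348). The amino acid list lost its call without ERRγ library 1 (camera adjusted p = 0.0607), ERRγ library 2 (0.157) or GFP library 1 (0.106), and with library totals (0.0523), no filter (0.105) or the 5 CPM filter (0.0825). Without GFP library 1 and without GFP library 2, so did Hk1 (adjusted p = 0.0659 and 0.0542), Slc16a1 (0.109 and 0.0799) and Idi1 (0.13 and 0.132), and without GFP library 2 alone Ldhb (0.0591) and Cbs (0.0636).

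Acinar identity genes were low in both groups and showed no shift with ERRγ that passed the test as a list. Ptf1a, a transcription factor that specifies acinar cells, had no count in any library, which allows up to 0.268 to 0.307 CPM. Bhlha15, which encodes the secretory factor MIST1, had 15 and 15 counts with ERRγ and 19 and 11 with GFP (log2 fold change −0.05, SE 0.62, adjusted p = 0.975). Carboxypeptidase A1, Cpa1, had 21 and 9 counts against 44 and 6 (log2 fold change −0.84, SE 0.91, adjusted p = 0.636), and its log2 fold change was 1.34 without GFP library 1 and −1.69 without GFP library 2. The ductal keratin gene Krt19 stood at 979 ± 253 and 1019 ± 83.3 CPM (log2 fold change −0.06, SE 0.19, adjusted p = 0.898), and the ductal factor Sox9 at 367 ± 74.4 and 380 ± 57.1 CPM (log2 fold change −0.05, SE 0.18, adjusted p = 0.911). Between fits that each left out 1 library, the log2 fold changes of Bhlha15 (−0.46 to 0.50), Krt19 (−0.35 to 0.18) and Sox9 (−0.27 to 0.15) changed sign. All digestive enzyme genes together took 0.015% and 0.0117% of counts with ERRγ and 0.0178% and 0.0072% with GFP. Of 20 such genes tested, the trypsinogen gene Prss2 rose 6.88-fold, also when adjusted over the list alone, with the caution that its family shares reads (median −0.50, camera adjusted p = 0.494). Their median difference between the libraries of a group, library 2 minus library 1, was −0.91 with ERRγ and −2.06 with GFP, and the islet markers moved the same way, by −1.50 and −2.42. Of 13 islet genes none passed, and none when adjusted over the list alone, with a median log2 fold change of −1.48 (camera adjusted p = 0.494). The digestive list turned upward and passed without GFP library 1 (camera adjusted p = 0.033) and passed downward without GFP library 2 (1.38e-06), and the islet list did likewise (0.033 and 2.96e-05). The call for Prss2 ended without GFP library 1 (adjusted p = 0.072) or GFP library 2 (0.0963).

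None of the 8 acinar transcription factor genes tested passed, nor did any when adjusted over the list alone (median 0.24, camera adjusted p = 0.494). In the zymogen granule and secretion list, the muscarinic acetylcholine receptor gene Chrm3 rose 3.21-fold, Rab27b rose (log2 fold change 0.88) and Muc1 fell (−0.62), out of 13 genes and with the same number when adjusted over the list alone (median 0.04, camera adjusted p = 0.674). The ductal and acinar-to-ductal metaplasia list moved both ways. Car2, a carbonic anhydrase of duct cells, rose 10.4-fold, from 5.40 ± 0.988 to 56.5 ± 6.68 CPM (adjusted p = 0.000208), and the chloride channel gene Cftr (log2 fold change 1.25) and the transcription factor gene Klf4 (2.18) rose. The keratin genes Krt7 (−0.65) and Krt8 (−0.66), S100a6 (−0.80) and the annexin gene Anxa1 (−1.19) fell. That made 3 up and 4 down of 28 genes, the same when adjusted over the list alone, with a median of −0.14, a mean of 0.06 and a camera direction of down (adjusted p = 0.47). Without GFP library 1 and without GFP library 2 the call for Chrm3 ended (adjusted p = 0.11 and 0.179), and that for Car2 held. Those for the other 8 genes named here as rising or falling ended without GFP library 1 (0.0754 to 0.312) and, apart from Anxa1 (0.0438), without GFP library 2 (0.0833 to 0.286). The log2 fold change of Klf4 was 1.53 without ERRγ library 2.

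Inflammatory and interferon genes included several falls, and no rise over all genes tested. Ccl2 fell 3.93-fold, from 52.7 ± 10.5 to 13.4 ± 2.82 CPM, and Saa3, an acute phase apolipoprotein gene, fell 5.33-fold, from 10.8 ± 4.82 to 2.02 ± 0.079 CPM. Its relatives Saa1 (log2 fold change 3.35, adjusted p = 0.138) and Saa2 (3.68, adjusted p = 0.15) leaned the other way and did not pass. Ifit3, an interferon-induced antiviral gene, fell 8.38-fold, from 8.45 ± 0.233 to 1.01 ± 0.802 CPM, and Ddx58, which encodes the RNA sensor RIG-I, fell 2.37-fold, from 27.5 ± 5.72 to 11.5 ± 4.28 CPM. Cd14, a coreceptor for bacterial lipopolysaccharide, fell 1.66-fold. Of 21 pancreatitis-associated acute phase genes listed, 15 were tested. All of the list's Reg genes were too low to test, so its result does not cover them. Ccl2 and Saa3 were the 2 of 15 that fell, also when adjusted over the list alone (median −0.31, camera adjusted p = 0.0102, and 0.749 with an estimated correlation). Cxcl5 in that list was not past the threshold (log2 fold change −1.07, adjusted p = 0.0966). Its log2 fold change was −0.61 without ERRγ library 1 and −1.76 without ERRγ library 2. The list's median member was 1.02 higher in ERRγ library 2 than in ERRγ library 1, and without ERRγ library 1 the list turned upward and lost its call (camera adjusted p = 0.228). In the interferon list Ifit3 and Ddx58 were the 2 of 21 genes that fell, 6 when adjusted over the list alone. The list's median was −0.63 (camera adjusted p = 0.000337, and 0.411 with an estimated correlation). Isg15 there did not pass (log2 fold change −1.48, adjusted p = 0.0714), and was at −1.10 without ERRγ library 1 and −1.97 without ERRγ library 2. Cd14 was the 1 of 6 macrophage and leukocyte genes that passed; 1 rose and 1 fell when adjusted over the list alone (median −0.40, mean 0.06, camera direction down, adjusted p = 0.494). The log2 fold change of Ifit3 went from −3.07 to −2.41 without ERRγ library 1 and −4.21 without ERRγ library 2. Without GFP library 1 the calls for Ccl2 (adjusted p = 0.0559), Saa3 (0.0587), Ifit3 (0.162), Ddx58 (0.335) and Cd14 (0.312) ended, as did those for Saa3 (0.191), Ifit3 (0.143), Ddx58 (0.134) and Cd14 (0.213) without GFP library 2.

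Of 24 oxidative stress genes 6 rose, while 2 of 25 genes of the unfolded protein response fell. Sod2, the superoxide dismutase of the mitochondrial matrix, rose 2.52-fold, from 68.5 ± 3.27 to 173 ± 3.42 CPM, and the peroxiredoxin gene Prdx5 rose 2.02-fold, from 127 ± 7.83 to 256 ± 17.0 CPM. Gstm1, a glutathione transferase, rose 2.87-fold. The endoplasmic reticulum protein genes Pdia4 and Manf fell 1.59-fold and 1.63-fold. The oxidative stress list had 6 of 24 genes up and none down, and 9 up and 2 down when adjusted over the list alone (median 0.25, camera adjusted p = 0.0149; adjusted p = 0.411 with an estimated correlation). Without GFP library 2 that camera call ended (adjusted p = 0.0685). Of 25 unfolded protein response genes, Pdia4 and Manf fell and Eif2ak3, which encodes the sensor kinase PERK, rose 1.59-fold; 1 rose and 8 fell when adjusted over the list alone (median −0.27, camera adjusted p = 0.0363; adjusted p = 0.485 with an estimated correlation). That call ended without ERRγ library 1 (camera adjusted p = 0.2) or GFP library 2 (0.0555). In the ATF4 and integrated stress response list Cth, the cystathionine γ-lyase gene, rose 2.92-fold and Ppp1r15a, which encodes the phosphatase subunit GADD34, rose 3.23-fold, out of 22 genes; 6 rose and 2 fell when adjusted over the list alone (median 0.30, camera adjusted p = 0.0371; adjusted p = 0.763 with an estimated correlation). Shmt2 there did not pass (log2 fold change 0.57, adjusted p = 0.0689), and was at 0.706 without ERRγ library 1. The list lost its camera call without ERRγ library 2 or GFP library 1. Ppp1r15a had a log2 fold change of 1.69, and of 0.92 without ERRγ library 2 and 2.19 without ERRγ library 1. Without GFP library 1 and without GFP library 2 the calls for Prdx5 (adjusted p = 0.127 and 0.0806), Pdia4 (0.206 and 0.169), Manf (0.259 and 0.113), Eif2ak3 (0.327 and 0.258) and Ppp1r15a (0.265 and 0.191) ended, and without GFP library 1 alone those for Sod2 (0.0587), Gstm1 (0.0637) and Cth (0.0927). Prdx5, Manf, Ppp1r15a and Shmt2 overlap other coding genes.

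Immediate early genes, which respond within minutes to hours to growth factors and stress, stood apart between the ERRγ libraries. Fosb had 115 and 959 counts in ERRγ libraries 1 and 2 and 54 and 60 with GFP (log2 fold change 3.26, SE 0.86, adjusted p = 0.0651). Zfp36 had 140 and 1037 against 89 and 119 (2.53, adjusted p = 0.1) and Fos 1199 and 3111 against 693 and 1055 (1.32, adjusted p = 0.104). None of the 19 genes passed, nor did any when adjusted over the list alone, although the list did (median 1.10, camera adjusted p = 0.0363; adjusted p = 0.763 with an estimated correlation). Its median member was 1.52 higher in ERRγ library 2 than in ERRγ library 1, and 0.00 between the GFP libraries. Without ERRγ library 2 the list passed in the downward direction (camera adjusted p = 0.0283), and Fosb, Zfp36 and Fos were at log2 fold changes of 0.91, 0.33 and 0.37; with the 5 CPM filter the list did not pass (0.0678). Without ERRγ library 1, Fosb, Zfp36 and Fos were at log2 fold changes of 4.12, 3.37 and 1.89.

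Cell cycle, apoptosis and autophagy lists did not pass. The G1 cyclin gene Ccne1 rose 2.38-fold, from 15.8 ± 1.86 to 37.5 ± 1.67 CPM, and Ccnd2 fell (log2 fold change −0.75), in a cell cycle list with 6 up and 1 down of 26 genes, or 10 and 4 when adjusted over the list alone (median 0.13, camera adjusted p = 0.138). The anti-apoptotic gene Bcl2 fell 1.74-fold and was the 1 of 20 p53 target and apoptosis genes that passed; 2 rose and 1 fell when adjusted over the list alone (median 0.09, camera adjusted p = 0.674). Gabarapl1, an autophagosome gene, rose 1.94-fold and was the 1 of 24 autophagy and lysosome genes that passed, also when adjusted over the list alone (median −0.01, mean 0.11, camera direction down, adjusted p = 0.935). Without GFP library 1 and without GFP library 2 these calls ended for Ccne1 (adjusted p = 0.0754 and 0.0901), Ccnd2 (0.258 and 0.126), Bcl2 (0.204 and 0.138) and Gabarapl1 (0.209 and 0.179). The cell cycle list passed without GFP library 1 (camera adjusted p = 0.0153) and the p53 list without ERRγ library 1 (0.0239), both upward.

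Markers of other pancreatic cell types did not pass as lists. The stellate cell and fibroblast list had 20 genes tested and the endothelial list 11, with none past the threshold in either over all genes or when adjusted over the list alone (medians −0.13 and 0.19, camera adjusted p = 0.389 and 0.494). Fabp4, a fatty acid carrier of adipocytes, rose 7.19-fold, from 0.884 ± 0.527 to 6.51 ± 1.52 CPM. It was the 1 of 6 erythrocyte and adipocyte genes that passed, also when adjusted over the list alone (median 1.54, camera adjusted p = 0.076), and its call ended without GFP library 1 (adjusted p = 0.193) or GFP library 2 (0.0833), the log2 fold change going from 2.85 to 3.64 without the latter. The stellate list passed in the downward direction without ERRγ library 1 (camera adjusted p = 0.0221) or GFP library 2 (0.0061), and the macrophage list without ERRγ library 2 (0.0328). The erythrocyte and adipocyte list passed upward without ERRγ library 1 (0.0489), GFP library 1 (0.033) or GFP library 2 (0.0433).

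Of the 31 lists tested, 16 passed with camera's preset correlation, 13 upward and 3 downward. With an estimated correlation 0 passed after adjustment (adjusted p from 0.411 to 0.977) and 1 at an unadjusted p under 0.05. By fry 11 lists passed, 10 of them also by camera: the respiratory chain lists, the TCA cycle, mitochondrial import and dynamics, the mitochondrial ribosome, creatine and striated muscle, oxidative stress and interferon. The fry adjusted p of these 10 lists lay between 0.043 and 0.0455, just under the threshold of 0.05. Glycolysis (fry adjusted p = 0.249), acute phase (0.545), unfolded protein response (0.171), ATF4 (0.374), amino acid (0.0994) and immediate early genes (0.616) passed by camera and not by fry, and the erythrocyte and adipocyte list by fry alone (0.0435).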

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

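The removal of Rn45s and the summing of rows with a shared symbol were chosen after seeing the data; the other alternatives were not. The 5 CPM filter left 4 of the 80 named genes and 3 of the 31 lists untested. Counts of genes higher and lower stayed within 1.5 times of 661 and 233 under the other scalings (627 to 690 higher, 169 to 252 lower), DESeq2 (757 and 342), limma-voom (630 and 241), the 5 CPM filter, and the removal of abundant genes or Rn45s. With no filter they were 1271 and 738 (63.3% higher), at an adjusted p of 0.1 they were 1063 and 546, and with a log2 fold change of at least 1 they were 404 and 71 (85.1% higher); the last pair differ by construction, and for the filter the cause was not tested. With the replicate number as a block, 776 genes were higher and 315 lower, 649 and 232 of them shared with the fit without it. The libraries were not taken as paired, since the labels do not state that equal numbers mark a shared day or animal. Deviations of same-numbered libraries correlated by 0.007 across all genes, a value that cannot exclude pairing. Digestive enzyme and islet genes were higher in both libraries numbered 1. The block took 2 further lists past the threshold, ERR receptors (camera adjusted p = 0.0415), which holds the introduced gene Esrrg, and islet (0.0165). It also took 4 named genes, Cxcl5, Shmt2, Fosb and Fos, past the threshold. The direction of the autophagy list turned (camera adjusted p = 0.886).

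Leaving out each library in turn gave 92 to 1597 genes higher and 7 to 1098 lower. Fewest were called without a GFP library, when the lone sample is assumed to vary like the ERRγ pair, which differed most (SD of log2 CPM differences 0.6, against 0.491 for GFP). Without an ERRγ library the lone sample is assumed to vary like the GFP pair. A difference between the ERRγ libraries then no longer counts against a call, so calls gained in these fits are not evidence of a change. The log2 fold change of Esrrg ranged from 3.81 to 7.12, and it was 5.46 with limma-voom, where its call ended; the cause was not tested. Of 66 named genes past the threshold, 60 kept it in every fit of all 4 libraries that tested them. Esrrb, counted among these 60, was too low to test with the 5 CPM filter. Cd14 lost its call with DESeq2 size factors (adjusted p = 0.0504) and Ppp1r15a with DESeq2 (0.0576). Mrpl12 and Ddx58 lost theirs with upper-quartile factors (0.0517 and 0.0513) or totals (0.0539 and 0.0656). Serpinb2 (0.119) and Esrrg lost theirs with limma-voom. Calls were gained by Isg15 and Shmt2 with DESeq2 (0.0489 and 0.0413), by Cxcl5 and Fosb with library totals (0.0487 and 0.043), and with no filter by these 4 and by Ckmt1, Slc7a8, Zfp36 and Fos (5.78e-37 to 0.0151) and the erythrocyte and adipocyte list (0.0126). The log2 fold changes of 5 named genes that did not pass changed sign when a library was left out: Esrra (−0.12 to 0.072), Bhlha15 (−0.46 to 0.50, and 0.041 with limma-voom), Cpa1 (−1.69 to 1.34), Krt19 (−0.35 to 0.18) and Sox9 (−0.27 to 0.15); the cause was not tested.

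Between 14 and 18 lists passed in every camera fit with the preset correlation, 11 with fry and 0 with an estimated correlation. Camera then takes the 2 residual degrees of freedom of the fit in place of a number set by the genes tested. By construction this raises p, and lists whose estimated correlation was below the preset 0.01, such as interferon (−0.044), lost their calls too. Other lists had estimated correlations far above 0.01, such as complex I (0.2), complexes II and III (0.493), ATP synthase (0.276), the TCA cycle (0.384) and glycolysis (0.857). A higher correlation also raises p, so their loss cannot be laid to the degrees of freedom alone. Lists that turned direction without a library, with the lowest and highest camera adjusted p, were digestive enzymes (1.38e-06 to 0.86), zymogen granule (0.462 to 0.908), acute phase (5.78e-17 to 0.228), autophagy (0.158 to 0.93), p53 (0.0239 to 0.767), immediate early (9.87e-24 to 0.045), islet (2.96e-05 to 0.444), stellate (0.0061 to 0.696) and endothelial (0.0916 to 0.919). Autophagy also turned with library totals (0.944) and fry (0.877), zymogen granule with no filter (0.94) and digestive enzymes with the 5 CPM filter (0.448); the cause was not tested. The count filter left 20 of 33 digestive enzyme, 13 of 20 islet and 15 of 21 acute phase genes. It left 10 of 25 creatine and striated muscle, 6 of 26 macrophage and 6 of 14 erythrocyte and adipocyte genes. The other members of these lists were too low to test at this depth.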

Other observations

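Apart from the single-gene tests of Cldn1 and Krt19, the gene groups in this part, their tests and the tests of explanations were chosen after the results were seen, so they describe these libraries and are not independent evidence. Genes of the trophoblast, the cell layer that forms the placenta, and of the early embryo were among the genes that appeared with ERRγ. Other genes that rose from no GFP count were in neither group, such as Lcn4 (125 and 102 counts in ERRγ libraries 1 and 2), Umod (52 and 68) and Pgr (45 and 51). Whether trophoblast and embryo genes were more frequent among such genes than those of other tissues was not tested. Besides Prl3d1 and Prl3d2, their near-identical relative Prl3d3 had 77 and 31 counts and none with GFP (at least 17.2-fold higher), and the trophoblast transcription factor gene Tfap2c had 32 and 38 and none (at least 11.5-fold higher). The germ cell and oocyte gene Dppa3 had 34 and 46 counts and none with GFP (at least 13.2-fold higher), and Nr0b1, which encodes the nuclear receptor DAX1, had 30 and 14 and none (at least 7.05-fold higher). Of 60 trophoblast and placental genes listed, 17 passed the count filter, some such as Prl3d3 and Tfap2c through their ERRγ counts alone, so that the count and median cover only detected members; of these 7 rose and none fell (median log2 fold change 2.44, also with the genes without GFP counts at their lower bound; camera adjusted p = 3.9e-11; adjusted p = 0.0569 with an estimated correlation). Of 31 early embryo genes, 15 passed the filter and 6 of them rose (median 0.13, camera adjusted p = 0.000596, and 0.108 with an estimated correlation). Some of these, Dppa3, Nr0b1 and Esrrb among them, also passed the filter through their ERRγ counts alone. The counts and tests of both lists therefore cover only detected members, and cannot decide whether either group as a whole rose. When adjusted over the list alone, 9 trophoblast and 6 early embryo genes rose. Pou5f1 and Nanog did not pass (adjusted p = 0.706 and 0.365). The near-identical Ly49 receptor genes of natural killer cells, Klra4, Klra12, Klra15 and Klra18, had 82 to 237 counts in ERRγ library 1 and 75 to 201 in library 2, against 0 to 9 with GFP; reads of these copies can be shared, and Klra2 did not pass (2 and 16 counts against 8 and 12). The 4 Ly49 calls held without any single library, whereas those for Prl3d3, Tfap2c, Dppa3 and Nr0b1 ended without GFP library 1 (adjusted p = 0.0955 to 0.2) or GFP library 2 (0.0806 to 0.169), and Nr0b1 was too low to test without ERRγ library 1.

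Of 28 keratin, claudin, intermediate filament, integrin, desmosome and plakin genes 10 fell and none rose with ERRγ, Cldn1, Krt6a (log2 fold change −1.53), Krt17 (−1.07), the integrin gene Itgb4 (−0.72) and the intermediate filament gene Nes (−1.10) among those that fell (camera adjusted p = 1.9e-08; adjusted p = 0.0569 with an estimated correlation). The same number fell when adjusted over the list alone, and Krt19 and Krt18 did not pass. Of 22 target genes of the growth regulators YAP and TAZ, 4 fell and 1 rose, and 8 fell and 3 rose when adjusted over the list alone. Ankrd1 (−0.86), Axl (−1.01), F3 (from 713 to 357 CPM) and Lats2 (−0.66) were the falls and Igfbp3 (0.85) the rise. The list passed by camera (adjusted p = 0.0293, and 0.173 with an estimated correlation) but not by fry (adjusted p = 0.0514). Its camera call did not hold in every fit that left out a library. Apart from Cldn1, the calls of the genes named in this paragraph as falling or rising ended without GFP library 1 (0.0566 to 0.313) and, apart also from Krt6a (0.0342) and Nes (0.049), without GFP library 2 (0.0574 to 0.208).

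ERRγ library 2 held more transcript than ERRγ library 1 of hypoxia genes as well as of immediate early genes: Adm had 271 and 2958 counts, Ndrg1 1017 and 9197. Of 22 hypoxia genes outside the glycolysis list, 1 rose and 1 fell between the groups, and 9 rose and 1 fell when adjusted over the list alone. The list's median was 1.31 (camera adjusted p = 0.000596, and 0.406 with an estimated correlation). Its camera call did not hold in every fit that left out a library. A graded response to the amount of Esrrg transcript, which differed by 3.31 (log2), would raise these genes in library 1 too, where Esrrg was already 14.1 times the GFP mean. The 61 immediate early, glycolysis and hypoxia genes lay there a median of 0.166 above GFP (quartiles −0.20 and 0.53), which leaves open a response that needs more Esrrg. That median pools lists that did not move alike. Without ERRγ library 2 the glycolysis list still pointed upward, whereas the immediate early list pointed downward. Stress or oxygen shortage of library 2's culture would raise the hypoxia genes, which differed by a median of 1.459 (quartiles 0.89 and 2.55), while respiratory chain genes differed by 0.12. These explanations cannot be told apart, because 1 library held both the higher Esrrg level and the higher stress genes.

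The Esrrb counts could be reads of the introduced Esrrg transcript placed at a related gene. They would then follow Esrrg between the ERRγ libraries, but 68% of Esrrb counts (exact 95% interval 53.3 to 80.5) lay in library 2, against 89.9% of Esrrg counts. Were all Esrrb counts of library 2 misplaced reads, its ratio would give an expected 3.8 of the 16 Esrrb counts in library 1. That value has no interval and takes the ratio to be equal in both libraries. Expression of Esrrb itself stays open, and no further biological test was made.

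Digestive enzyme and islet genes were higher in both libraries numbered 1 than in those numbered 2. Slower loss of acinar identity in these cultures was taken to leave islet genes alone, which was not tested. The islet median difference (log2, library 1 minus 2) was at least 1.502 in both groups. Islet genes were part of the pattern as first seen, so their difference is no separate test of this explanation. More residual pancreatic tissue in these libraries would raise markers of other pancreatic cells too; stellate and endothelial medians were 0.089 to 0.509 higher in libraries 1, too little to decide, so this stays open. Ins2 had 153 and 33 counts with ERRγ and 597 and 130 with GFP. Whether the libraries of one number came from a shared preparation cannot be told apart from coincidence: their deviations correlated by 0.007 over all genes, but a few contaminating transcripts would not move that value. The labels give the numbers no meaning.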
